A study of Rattus norvegicus with 6 samples.

How the data were processed

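Hippocampal RNA of male Wistar rats was measured on 6 one-colour Agilent expression arrays. Per the labels, 1 array held control RNA and each of the others held RNA from 1 of 5 time points after permanent occlusion of both common carotid arteries, namely day 21, day 35, day 45, day 55 or day 70. Per the labels' protocols, RNA was isolated with TriPure reagent, pooled, and amplified and labelled with the Agilent Low RNA Input Linear Amplification kit PLUS. The number of animals behind each pool, and whether the control animals had a sham operation, are not given in the sources used here. The labels name Cy5 as the dye, whereas the scanner files hold the columns of 1 colour, the green channel, and these columns were used.

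The authors deposited 1 scanner file per array, and per the file headers each was read with Agilent Feature Extraction 10.7.3.1 on design 028282, whose probe positions refer to genome build rn4. The intensity of each spot, per the file headers, is a processed signal from which the local background had been subtracted and whose trend across the array had been removed, with no scaling between arrays. The authors also deposited a table of values on a linear intensity scale for 41507 of the 42877 non-control spots. On every array its values had a rank correlation of 1.00 with the median spot signal minus the local background. Its columns had medians of 298.0 to 298.4 and 75th percentiles of 1432.0 to 1432.5, as quantile normalization gives. How that table was made is not given in the sources used here, and it served as an alternative.

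Spots that Feature Extraction marked as outliers were left out, between 346 and 470 per array, and saturated spots were kept. The log2 of the processed signal was scaled by subtracting the array's own 75th percentile over all non-control spots, and spots of the same probe were averaged. The arrays carried 30367 probes of 60 bases, of which 1390 were printed 10 times and 28977 once. Probes were named through a table of current rat RefSeq genes (assembly GRCr8), from which only names were taken. The accession in the files matched for 17328 probes, the symbol for 2610 and a synonym for 340. The name in the file was kept for 189 probes, and 9900 probes stayed without a gene name. The result was 17166 genes, each represented by its probe with the highest mean value over the 6 arrays, since 2991 genes had more than 1 probe. All coordinates are those of the array files, in build rn4.

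Differences are log2 values of a time point minus the control array. A gene entered a comparison where its probe was well above background on at least 1 of the 2 arrays. Where the probe was not well above background on the dimmer array, the lowest signal well above background on that array, or the probe's own signal if higher, took its place, and the difference is a lower bound, written as at least so many fold. A saturated brighter spot also gives a bound. A gene was counted as higher or lower at a difference of at least 2-fold. Genes not well above background on either array have no difference between them. Genes saturated on both arrays have no measured difference either, but they entered their lists as unchanged. The distance between 2 arrays is the SD, over the 12172 genes well above background on all 6 arrays, of their log2 differences.

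With 1 array per group no spread between animals could be estimated, so no p-values or standard errors are given and the number of arrays limits the precision. Probes printed 10 times give the technical spread within an array, a median SD of 0.051 to 0.074 log2 units between spots. From that source alone the SD of a difference between 2 arrays would be 0.083. The share of spots well above background was 74.5 to 80.2%.

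For 29 gene lists the median difference of the members was ranked among 10000 random lists of the same size matched on mean signal in 20 bins. Members called measured in a list include those saturated on both arrays, which counted as unchanged. A list is said to stand apart below the 2.5th or above the 97.5th percentile, which describes these arrays and is no test of the occlusion. Of 145 such percentiles 7.25 would lie outside by chance if genes were independent, and more because genes of a list vary together. The lists covered synaptic vesicle genes, glutamate receptors with the postsynaptic density, GABA signalling, cholinergic signalling, immediate early genes, neurotrophic factors, neurogenesis with proliferation, reactive astrocytes, hypoxia, cytokines, antigen presentation with complement, oxidative phosphorylation, antioxidant defence, heat shock with the unfolded protein response, amyloid and tau processing, apoptosis, the circadian clock and the glucocorticoid response. Marker lists covered microglia, astrocytes, oligodendrocytes, endothelium with pericytes, choroid plexus, meninges, red blood cells, thalamus, striatum, dentate gyrus granule cells and pyramidal cells of CA1 to CA3.

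Genes named in the text came from a rule. At each time point it took the 6 genes most above and the 6 most below the control, by at least 2-fold. It also took up to 10 genes of each direction that differed at all 5 time points, the 10 with the widest range among genes with opposite differences, 4 per direction at each step between consecutive arrays, and the 4 members of each list with the largest differences. Further list members were named as examples after their values were seen. The comparisons, the lists, the naming rule and the first set of processing choices below were fixed before the data were examined.

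Other processing choices tried were quantile normalization, normexp background correction with an offset of 50, the authors' deposited table, the mean of all probes of a gene, genes well above background on all 6 arrays, no filter on dim probes, thresholds of 1.5-fold and 3-fold, the mean of the other 5 arrays as the baseline, the mean instead of the median of a list, and lists without shared genes. Added after the data had been seen were the removal of genes bright on 1 array alone (at least 2-fold above each of the other 5 arrays), a lowess correction of the trend with signal level (span 0.2), a correction for probe GC content within 10 bins of level, and the removal of the day 21 array. Chance values for overlaps that share the control array came from 20 simulated sets of 6 unchanged arrays, drawn with the residuals of the arrays of the second slide.

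The counting and the list ranking were tested on simulated data for day 55 against control, over 12172 genes. Of genes simulated with a 2-fold change (1.0 log2 unit) 64.0% passed the threshold, against 92.0% at 1.5 log2 units and 100.0% at 2.0. Of 11952 unchanged genes 0.192% passed. The simulated noise was normal, with the spread between the day 55 and day 70 arrays of 1 slide. Their distance was 0.245, against 0.331 between control and day 55, so the rates are those of a quieter comparison. The number of simulated genes is that of the genes well above background on every array, so these rates do not cover dimmer genes. Limited to such genes, 283 genes were lower at day 55, against 681 without that limit. In the simulated sets of unchanged arrays 126.0 genes per day passed as lower and 120.4 as higher. Of 100 unshifted lists 96 lay inside the percentile range. The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with limma 3.58.1 for normexp.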

Results

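Chronic cerebral hypoperfusion, a lasting shortage of blood flow to the brain, was produced in male Wistar rats by permanently tying off both common carotid arteries. Expression in the hippocampus was then measured on 6 arrays. The control pool had 1 array, as had the pools taken at 21, 35, 45, 55 and 70 days. There were no replicates, so every difference describes 1 array of pooled RNA against another and carries no error. The title of the series speaks of regulation in phases, which makes the question when, and in which direction, gene expression differed from the control. The control, day 21 and day 35 arrays lay on one slide and the day 45, 55 and 70 arrays on another. Between 12427 and 13475 of 17166 genes were well above background on an array, and the 75th percentile of the signal ranged from 1243 to 1504 intensity units. Differences are log2 values of a day minus the control unless given as folds, and "at least" marks a lower bound where the dimmer array was not well above background.

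At day 21 genes of microglia, macrophages, complement and antigen presentation were far above the control. Spp1, which encodes the secreted glycoprotein osteopontin of activated macrophages and microglia, was 70.9-fold higher, a value averaged over 10 spots. Lgals3 (galectin-3) was 19.3-fold higher, Glipr1 16.1-fold and the lysosomal glycoprotein gene Cd68 15.2-fold. Tfec, a transcription factor gene of the macrophage lineage, was at least 21.1-fold higher, since it was not well above background on the control array. Genes of synapses stood lower at the same time, by much less, as with the AMPA receptor subunit Gria1 at -0.55 log2 units and the NMDA receptor subunit Grin1 at -0.56. In all, 499 genes were at least 2-fold higher and 259 at least 2-fold lower, of 13746 compared, and 374 and 138 of these were measured on both arrays.

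Of 17 microglial marker genes, all were above the control at day 21 and 11 were at least 2-fold higher. Their median was 1.32 log2 units (2.5-fold), above all 10000 random lists. Besides Cd68 (3.93), the IgG receptor gene Fcgr2b was higher by 2.92 (1.42 at its other probe), the lipid-sensing receptor gene Trem2 by 2.52 and the leukocyte phosphatase gene Ptprc by 2.25. Markers of surveying microglia differed less, with P2ry12 at 1.17, Tmem119 at 0.24 and Cx3cr1 at 0.07. For 16 of the 17 markers the day 21 array was the highest of the 6.

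Genes of antigen presentation and complement had the highest median of the 29 lists at day 21, 1.64 log2 units, at the 100th percentile. Of 21 measured members 13 were at least 2-fold higher and none was 2-fold lower. The invariant chain gene Cd74 was higher by 3.31 and the class II genes RT1-Da and RT1-Bb by 3.87 and 2.92, although the other probe of RT1-Bb stood at 0.89 and members of the RT1 family are alike and their probes uncertain. The central complement gene C3 was higher by 2.89, C2 by 2.19 and C1qb by 1.94. Among cytokines, chemokines and targets of NF-kappaB, 10 of 19 measured genes were at least 2-fold higher, and their median of 1.04 lay at the 100th percentile. The chemokine genes Ccl2 and Ccl3 were at least 14.9-fold and 11.3-fold higher, and Cxcl10 was higher by 3.24. The receptor antagonist gene Il1rn was higher by 1.87, whereas Tnf differed by 0.42 and Ptgs2 by -0.43.

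Reactive astrocyte genes had a median of 1.37 at day 21, at the 100th percentile, with 10 of 16 at least 2-fold higher and 1 lower. The intermediate filament genes Vim and Gfap were higher by 2.49 and 1.02, the complement inhibitor gene Serping1 by 3.29, Lcn2 by 5.67-fold and the hyaluronan receptor gene Cd44 by 2.08 (0.18 at another of its probes). The lower member was S1pr3 (-1.26). General astrocyte markers had a median of 0.19 (99.9th percentile), with Aqp4 at 0.67. Oligodendrocyte and myelin genes also had a median of 0.19 (100th percentile), with Mal at 0.74. None was at least 2-fold apart among 17 that include the saturated Mbp. Mbp, Aldoc, Apoe, Eno1 and Atp5f1a were saturated on all 6 arrays, which hides any difference in them, and they entered their lists as 0.

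Markers of tissue at the border of the hippocampus were higher at day 21 as well. Choroid plexus genes had a median of 1.39 (100th percentile), with 9 of 15 at least 2-fold higher. Ttr, which encodes the thyroid hormone carrier transthyretin, was saturated and at least 17.6-fold higher, Kcnj13 at least 11.3-fold higher and Sostdc1, read from 10 spots, 10.5-fold higher. Genes of the meninges and fibroblasts had a median of 1.19 (100th percentile), with 7 of 12 at least 2-fold higher, among them the collagen genes Col3a1 (2.31) and Col1a2 (1.97) and the growth factor gene Igf2 (1.65). Red blood cell genes had a median of 0.22 (98.3rd percentile). These facts stand beside the immune and glial values of the same pool.

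Synaptic genes were lower at day 21 by small amounts in nearly every member. Synaptic vesicle genes had a median of -0.29, below all random lists, and 17 of 18 were below the control, with Napa at -0.41 and Syn1 at -0.38. Glutamate receptor and postsynaptic genes had a median of -0.30, also below all random lists, with 20 of 21 below the control and none by 2-fold. The scaffold gene Dlg4 stood at -0.43 and the NMDA subunit Grin2b at -0.43. Pyramidal cell markers of CA1 to CA3 had a median of -0.24 (0.5th percentile), with Wfs1 at -0.59 and Neurod6 at -0.42. Of the neurotrophic genes, whose median of -0.10 lay at the 30.9th percentile and whose mean was 0.19, Bdnf stood at -0.58, while Igf1 was higher by 2.65.

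Smaller shifts at day 21 concerned stress and growth. Heat shock and unfolded protein response genes had a median of 0.32 (100th percentile), with 15 of 16 above the control, Sdf2l1 at 1.34 and Atf3 at 1.11. Neurogenesis and proliferation genes had a median of 0.21 (99.2nd percentile), made of cell cycle genes above the control (Cdk1 1.04, Top2a 0.77) and neuroblast genes below it (Sox11 -0.72, Dcx -0.47). The glucocorticoid response list, median 0.17 (99.8th percentile), held the metallothionein genes Mt2A (2.15) and Mt1 (1.30) beside Hif3a (-1.17). Apoptosis regulators had a median of 0.10 (97.9th percentile), with Bak1 at 0.59. The calls of the apoptosis, red blood cell, pyramidal cell, neurogenesis and glucocorticoid lists held under 6, 8, 9, 10 and 10 of 11 other processing choices, among which the mean of the list ended the apoptosis, pyramidal cell and neurogenesis calls. The hypoxia list did not stand apart, with a median of -0.05 (52.2nd percentile), a mean of 0.11, and Adm at 1.37 and Hk2 at 1.24. The other lists stayed inside the range. Their medians were -0.13 for GABA signalling, -0.22 for cholinergic signalling, -0.14 for immediate early genes, -0.07 for endothelium, -0.07 for oxidative phosphorylation, -0.01 for antioxidant defence, -0.08 for amyloid and tau processing, -0.15 for the circadian clock, 0.04 for thalamus, -0.09 for striatum and -0.23 for dentate gyrus granule cells. In the antioxidant list, whose mean was 0.10, Hmox1, the heme-degrading enzyme gene, was higher by 1.30.

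Among the genes most below the control at day 21, Elfn1 was at least 21.5-fold lower, the taste receptor gene Tas2r123 at least 9.76-fold, Tpbpa at least 9.09-fold, Hydin at least 8.33-fold and the olfactory receptor gene Or8b47 at least 8.3-fold, whereas Hcfc2 was measured on both arrays at -3.09. Apart from Hcfc2 and Tas2r123 these were bright on the control array alone, each from 1 spot. The highest olfactory receptor gene at day 21, Or1e1c (at least 17.5-fold), was likewise read from 1 spot, and receptors of these families are alike, so their names are uncertain. Of the 499 higher genes 360 were bright on the day 21 array alone, and 136 were left when all genes bright on 1 array were removed, a filter that by its construction also removes genes such as Spp1 that differ at day 21 only. Probes printed 10 times were bright on the day 21 array alone 44 times, where 18.0 were expected from probes printed once at their level. Normexp background correction gave 238 higher and 27 lower genes, and the values the authors deposited gave 368 and 112.

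**Figure D1:**
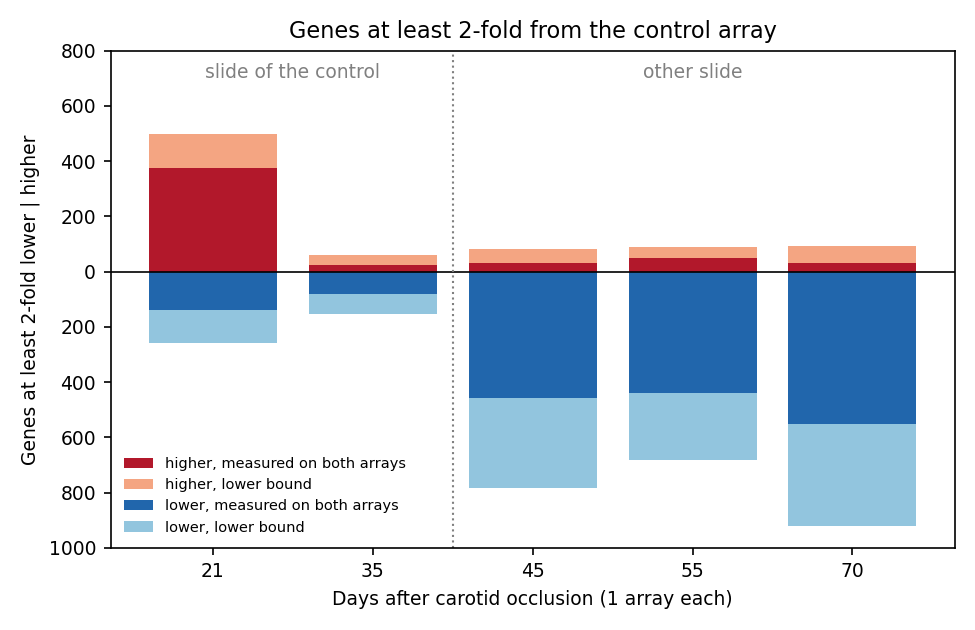
Bars show the number of genes at least 2-fold higher (above 0) or lower (below 0) than the control array at each day, 1 array each, with dark parts measured on both arrays, light parts lower bounds and a dotted line between the slides. Day 21 had 499 higher genes against 61 to 92 at the other days, and days 45, 55 and 70 had 783, 681 and 922 lower genes.

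**Figure D2:**
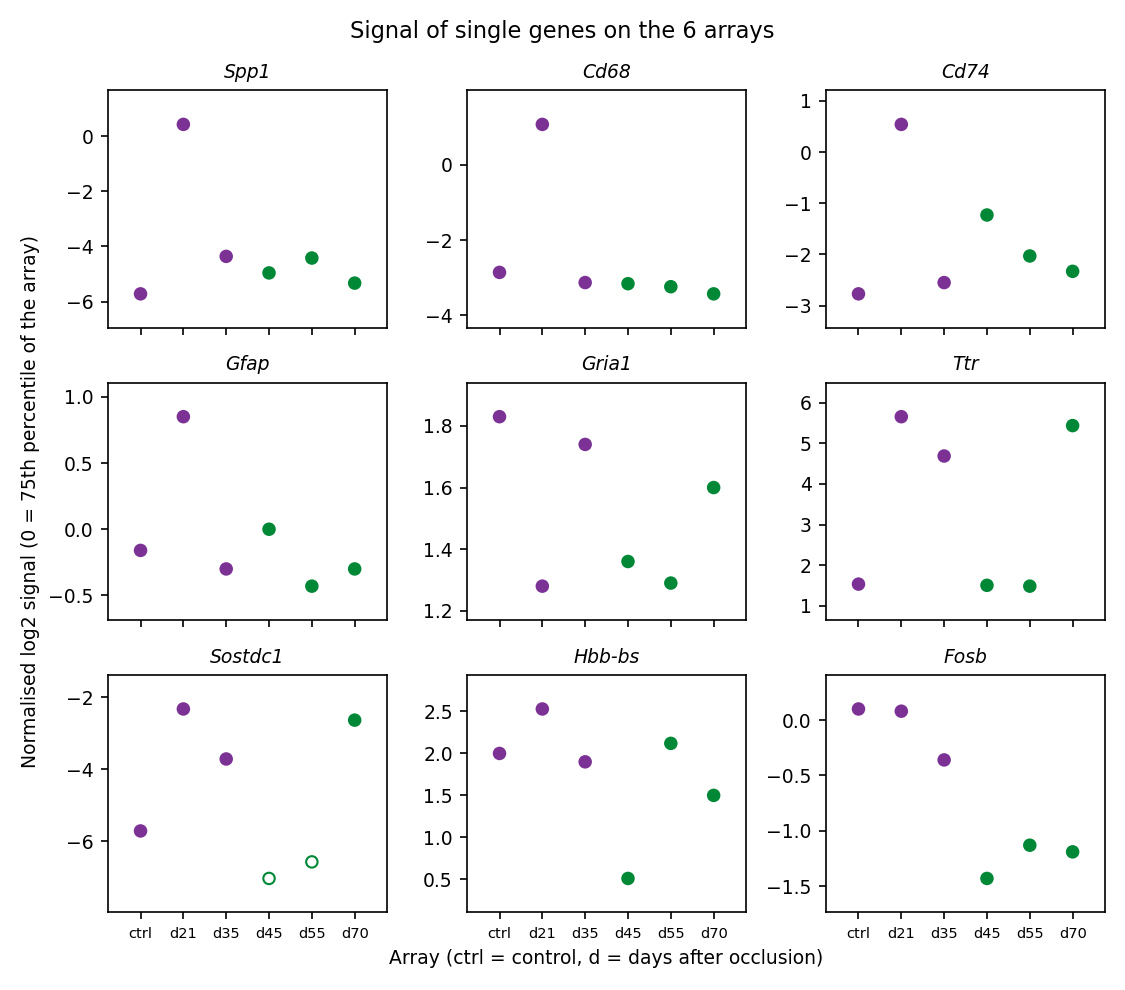
Points show the normalised log2 signal of 9 genes on each of the 6 arrays, where 0 is the 75th percentile of the array, purple marks the slide of the control, green the other slide and open points are not well above background. Spp1, Cd68, Cd74 and Gfap were highest at day 21, while Ttr and Sostdc1 were high at days 21, 35 and 70.

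By day 35 the immune and glial genes stood near the control again. Microglial genes had a median of -0.03 (42.0th percentile), antigen presentation and complement -0.03, reactive astrocytes -0.14 and cytokines -0.07, with Cd68 at -0.27 and Gfap at -0.14. Spp1 was 2.56-fold higher and RT1-Da 2.02-fold, and Spp1 stood at 0.76, 1.30 and 0.38 log2 units at days 45, 55 and 70. The control signals of Spp1 (-5.72) and RT1-Da (-5.89) enter all their differences. They lay near the lowest signal well above background on that array (-6.36), so the folds of both genes are uncertain in size. Choroid plexus genes again stood apart, with a median of 0.36 (100th percentile), 4 of 14 at least 2-fold higher, Ttr at 3.17, Kcnj13 at least 2.20 and Otx2 at 1.65, while meningeal genes had a median of 0.00. In this comparison, within 1 slide, 61 genes were at least 2-fold higher and 153 lower.

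Most vascular genes were below the control at day 35. Endothelial and pericyte genes had a median of -0.21 (0.3rd percentile) and 14 of 18 below the control, with the drug transporter gene Abcb1a at -1.49 and the pericyte gene Rgs5 at -0.54. As many members were below it at days 55 and 70, with medians of -0.16 inside the range (7.4th and 4.1st percentiles). Circadian clock genes had a median of -0.25 (0.1st percentile) with 10 of 16 below the control, Nr1d1 at -0.52 and Dbp at -0.47, although Tef stood at 0.94. The call was lost with the mean of the list (-0.10) and with the mean of the other 5 arrays as the baseline (-0.02). Heat shock and unfolded protein response genes had a median of 0.14 (100th percentile), with the chaperone gene Hspa5 at 0.48, a call lost with that baseline (0.06). Thalamic markers stood at 0.16 (99.8th percentile, Zic1 1.12 and Calb2 0.68) and striatal markers at 0.12 (99.1st percentile, Penk 0.25). Oligodendrocyte genes had a median of 0.10 (99.7th percentile, Mobp 0.28) and astrocyte markers -0.09 (1.8th percentile, Sox9 -0.50). The striatal, oligodendrocyte and astrocyte calls held under 6, 7 and 3 of 11 alternatives. Synaptic vesicle genes, at -0.29 on day 21, had a median of -0.01 at day 35, and glutamate receptor genes one of -0.05.

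Apart from Ttr, the genes most above the control at day 35 were each read from 1 spot and bright on that array alone, with Tas2r114 at least 3.75, Csap1 3.70, Airim 3.32, Pdx1 3.30 and Ikzf3 3.12 log2 units higher. The cytokine gene Il36g joined Elfn1, Tas2r123, Tpbpa, Hydin and Or8b47 among the lowest, at a bound of -3.36. Quantile normalization changed the split from 61 higher and 153 lower genes to 112 and 131. Normexp correction left 12 and 36.

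At days 45, 55 and 70 most of the genes past the threshold were lower than the control and dim. At day 45, 783 genes were lower and 82 higher, at day 55 681 and 89, and at day 70 922 and 92. Of the lower genes 92.7%, 93.0% and 93.1% were among the dimmest of 3 equal groups of genes by mean signal, against 4, 2 and 3 genes in the brightest group. The share was much the same for the lower genes of days 21 and 35 (93.1% and 92.8%) and for the higher genes of days 45, 55 and 70 (92.7%, 92.1% and 93.5%). Zp3r, which encodes a sperm protein, stood at -3.78, at least 19.8-fold lower and at -4.14 at the 3 days, and Smr3b, a salivary protein gene, at -3.44 on day 55. Klhl40 was at a bound of -3.33 and Gtsf2 at -3.18 on day 45. Smr3b, Klhl40 and Gtsf2 were bright on the control array alone and were at least 2-fold lower at days 21 and 35 too. The other probe of Gtsf2 stood at -0.21, -0.25 and -0.61 on days 21, 35 and 70. Of the 6 genes most below the control at days 45, 55 and 70, 5, 4 and 4 were bright on 1 array alone. These 3 arrays lay on another slide than the control, so the time after occlusion and the slide cannot be told apart here. Age also went with the day, from 12 weeks in the control to 13 weeks at day 21 and 17 weeks at day 70 per the labels. These ages are not what the days between the time points would give, so how far age differed between the pools is uncertain. Quantile normalization gave 200 higher and 297 lower genes at day 45, 183 and 412 at day 55 and 226 and 403 at day 70, a smaller excess of lower genes.

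**Figure D3:**
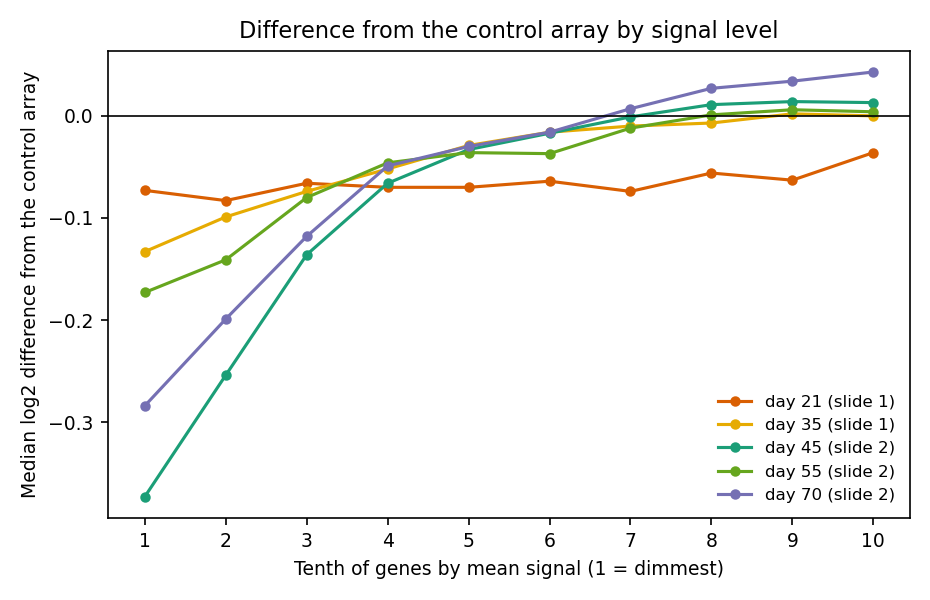
Lines show the median log2 difference from the control array (vertical axis) for 10 equal groups of genes ordered by mean signal from dimmest to brightest (horizontal axis), 1 line per day. In the dimmest group the medians were -0.373, -0.173 and -0.284 at days 45, 55 and 70, and in the brightest group all days lay between -0.036 and 0.043.

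Single members of several lists, most of them dim and singled out after their values were seen, were lower on the 3 later arrays while their lists were not all low. The hypoxia list had medians of 0.06, 0.00 and 0.04 at days 45, 55 and 70, and the heat shock list -0.05, 0.14 and 0.07. At day 55, 9 of the 19 hypoxia members were above the control and 9 below, so 0.00 is the value entered for a saturated member. The immediate early gene Fosb stood at -1.53, -1.23 and -1.29 at days 45, 55 and 70. The hypoxia-inducible genes Car9 (-1.21, -1.10 and -1.12) and Pfkfb3 (-0.90, -0.93 and -1.09), the hexokinase gene Hk2 (-0.98, -1.05 and -0.82) and the stress pseudokinase gene Trib3 (-1.65, -1.43 and -1.53) were lower too. The neuroblast transcription factor gene Sox11 stood at -1.15, -0.78 and -1.33, and the adhesion gene Nectin3 at -1.10, -0.81 and -1.01. Fadd, the adaptor of death receptors, was lower by bounds of -1.63, -1.99 and -1.96. Abcb1a was below the control on all 5 arrays, at -1.26, -1.49, -1.59, -0.96 and -1.33.

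At day 45 red blood cell genes had a median of -0.96, below all random lists, with all 6 measured members lower, among them the alpha globin gene Hba-a1 (-0.86) and the haemoglobin chaperone gene Ahsp (-1.07). The beta globin gene Hbb-bs was 2.8-fold lower, and globin genes are near-identical, so single members are uncertain. Immediate early genes had a median of -0.36 (below all random lists), with 15 of 16 below the control. Microglial genes had a median of 0.15 and antigen presentation genes 0.24, both at the 100th percentile, with RT1-Da at 2.30, Cd74 at 1.54 and RT1-Bb at 1.11, although the other probe of RT1-Bb stood at -0.51. The microglial call was lost with the mean of all probes of a gene. The microglial and antigen presentation medians turned to -0.23 and -0.09 when the mean of the other 5 arrays was the baseline, which holds the day 21 array. Glutamate receptor genes had a median of -0.12 (0.4th percentile), circadian genes -0.25 (1.6th), the hypoxia list 0.06 (99.0th) and the glucocorticoid list 0.12 (99.8th). Their calls held under 6, 4, 5 and 9 of 11 alternatives, and the mean of the hypoxia list was -0.11. Choroid plexus genes had a median of -0.10, with Ttr at -0.03. The cholinergic and neurogenesis lists had low medians, -0.45 and -0.37, inside the range for genes at their level (4.3rd and 3.8th percentiles). The acetylcholine synthesis gene Chat stood at -0.84 and the GABA receptor subunit gene Gabrb2 at -0.87.

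At day 55 few lists stood apart. Synaptic vesicle genes had a median of -0.14, below all random lists, with 17 of 18 below the control and Rab3a at -0.47 and Napa at -0.45. Heat shock and unfolded protein response genes had a median of 0.14 (100th percentile), with the inducible chaperone gene Hspa1b, read from 10 spots, at 1.37 and Hspa5 at 0.41. Red blood cell genes had a median of -0.21 (1.9th percentile) but a mean of 0.15, and the glucocorticoid list a median of 0.09 (98.0th percentile), held under 6 of 11 alternatives. The immediate early gene Egr3 was higher by 2.52 on this array alone from 1 spot, although its other probe stood at -0.53, while the list's median was 0.06 (95.6th percentile). The synaptic vesicle and heat shock calls were lost only with the mean of the other 5 arrays as the baseline, and the red blood cell call held under 7 of 11 choices. Microglial and choroid plexus genes had medians of 0.04 and -0.04.

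At day 70 choroid plexus genes stood apart once more, with a median of 0.84 (100th percentile), 6 of 14 at least 2-fold higher and Ttr at 3.91, Sostdc1 at 3.08, Otx2 at 1.32 and Folr1 at 1.01. Microglial genes had a median of 0.08 (97.2nd percentile) in the same pool, reactive astrocyte genes -0.12 and meningeal genes 0.01. Red blood cell genes were below the control again, median -0.70 and below all random lists, with Alas2 at -0.90 and Ahsp at -0.82. Immediate early genes had a median of -0.19 (0.3rd percentile, Ier2 -1.08), circadian genes -0.19 (1.3rd percentile), antigen presentation genes 0.09 (99.8th percentile), the glucocorticoid list 0.17 and dentate gyrus granule cell genes 0.17 (both 100th percentile). The calls of the immediate early, circadian, antigen, glucocorticoid and dentate lists held under 7, 4, 9, 9 and 10 of 11 alternatives, and the means of the last pair of lists were -0.01 and -0.11.

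**Figure D4:**
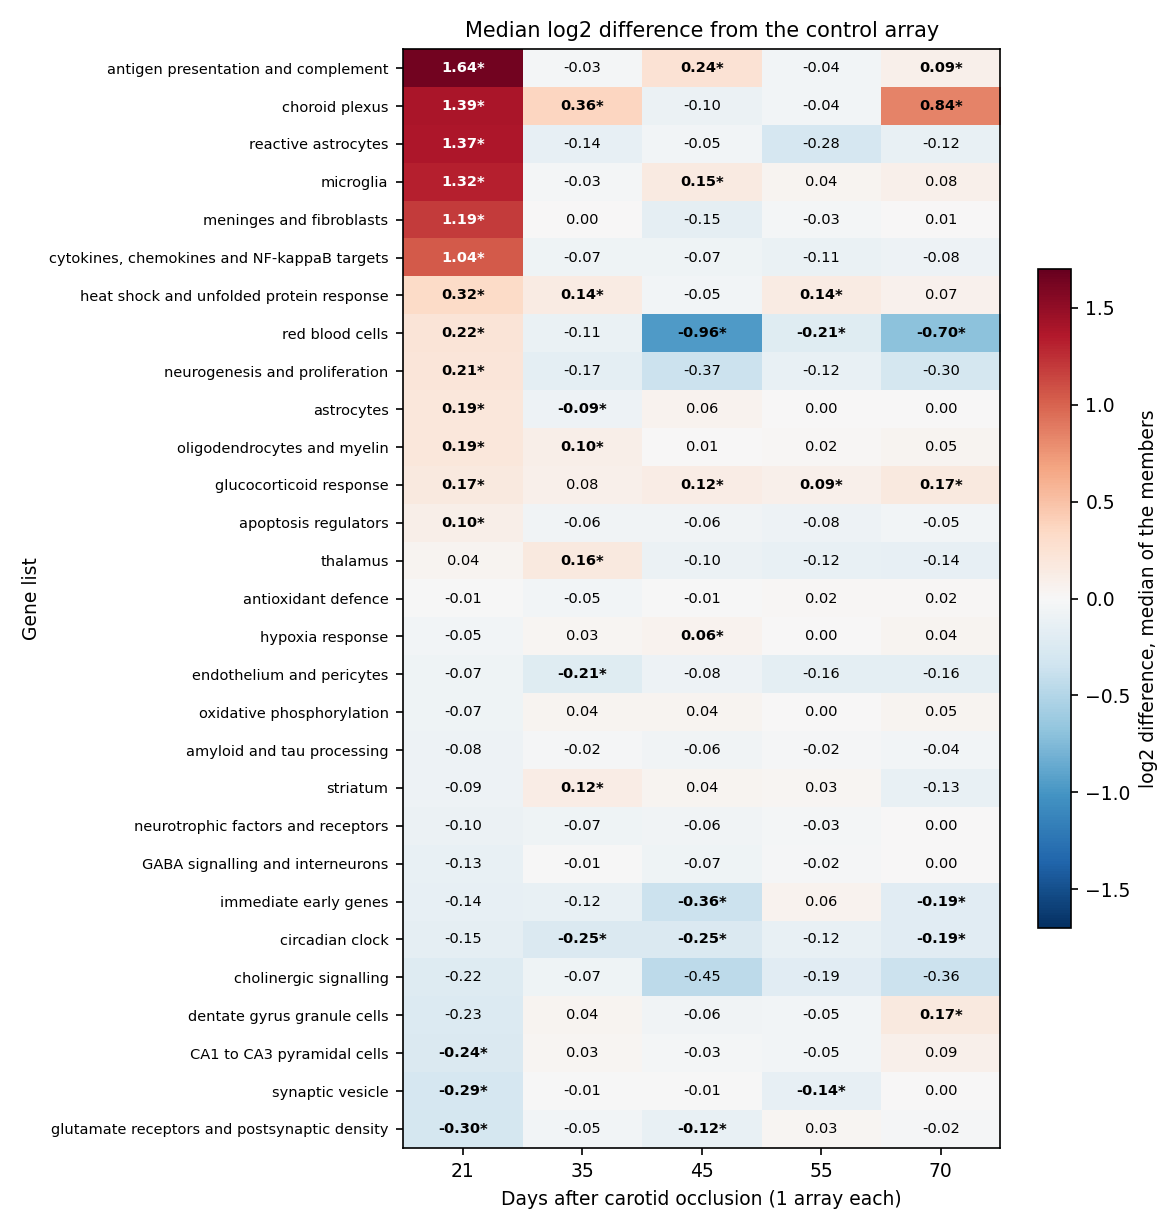
Colours and numbers show the median log2 difference from the control array for 29 gene lists (vertical axis) at each day after occlusion (horizontal axis, 1 array each), and bold values with an asterisk lie outside the range of most matched random lists. Day 21 held 13 lists apart above and 3 apart below, choroid plexus genes also stood apart at days 35 and 70, and red blood cell genes were at -0.96 and -0.70 at days 45 and 70. Under other settings the medians of microglia at day 45, antigen presentation at days 45 and 70, red blood cells at day 55 and the glucocorticoid list at days 55 and 70 changed sign, as did the means of the hypoxia list at day 45 and dentate gyrus genes at day 70.

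The genes most above the control at the later days were, apart from Ttr at day 70, all read from 1 spot, bounds and bright on 1 array. At day 45 they were C14h1orf146, Hoxc12, Lrsam1, Gprasp3, Izumo1 and Agr3, between 2.81 and 4.31 log2 units or more. On day 55 the list was Wfdc5, Atp1a4, Ces2e, Adamts12, Ccr4 and Cdh16, at least 3.16 to 4.56, and on day 70 Tore, Stard5, Il1rl1, Slco1a1 and Rnf19b, at least 3.78 to 4.43. Of the 82, 89 and 92 higher genes, 42, 41 and 63 were bright on their own array alone. With normexp correction the counts of lower genes were 105, 75 and 124 at days 45, 55 and 70.

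From control to day 21 499 genes were higher and 259 lower. From day 21 to day 35, on 1 slide, 613 genes were lower and 139 higher, with Spp1 at -4.79, Cd68 at -4.20 and Tfec at a bound of -4.51. From day 35 to day 45, across the slides, 526 genes were lower and 103 higher, with Ttr at -3.19. Without a filter on dim probes this step across the slides had the most genes, 1489 lower and 250 higher, against 734 and 774 from control to day 21. Within the second slide 99 genes were lower and 113 higher from day 45 to day 55, and 125 lower and 119 higher from day 55 to day 70. At these steps most of the named genes, such as Wfdc5 (at least 4.39 higher, then at a bound of -4.72), were bright on 1 array alone, and Tas2r123 was at a bound of -3.73 from day 45 to day 55.

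RT1-Da was the gene at least 2-fold higher at all 5 days, against a mean of 5.6 such genes in simulated arrays without an effect that share 1 control. At all 5 days 55 genes were lower, among them Elfn1, Tpbpa, Hydin, Or8b47, Il36g, Mzb1, Defa5, Gja6, Vom2r23 and Hist1h4m, against 52.5 simulated. By their definition these are the genes bright on the control array alone, and 27 of them were well above background on that array only. Opposite differences at different days were seen for 33 genes, against 7.3 simulated. The simulation had 120.4 higher and 126.0 lower genes per day. Measured were 499 higher genes at day 21 and 681 to 922 lower genes at days 45 to 70. More genes past the threshold give more opposite differences, so 33 against 7.3 does not show an excess of changes of direction. Of the 33 genes 23 were higher at day 21. The endocytic gene Ston1, for example, was higher by 1.34 at day 21 and stood at -2.06 at day 45. Cyp2j10 went from 2.54 at day 21 to -1.12 at day 55, and Tox2 from 2.99 at day 21 to a bound of -1.43 at day 70. Chit1, a macrophage chitinase gene, was higher by 1.54 at day 55 and stood at -1.46 at day 70, and Hk3 was higher by 2.03 at day 45 and at a bound of -1.02 at day 55. Of these 33 genes 11 were left without genes bright on 1 array, and 2 had opposite differences after normexp correction.

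Of the genes higher at day 21, 463 were at least 2-fold higher at no other day, where a day without a comparison counted as not higher. Of the 499 higher genes 379 were compared at all 5 days. The days 45 and 70 shared 645 lower genes, where independent lists would share 53.5 and simulated arrays without an effect that share the control shared 72.0. Days 45 and 55 shared 488 (39.5 if independent, 72.7 simulated) and days 55 and 70 603 (46.6 and 84.8). At all 3 days 464 genes were lower against 63.5 simulated, and 275 of them were not lower at days 21 and 35, against 1.9 simulated. The simulation had 126.0 lower genes per day, fewer than measured, and no difference between slides, so the excess holds the slide as well as the days. It had 120.4 higher genes per day, more than the 61, 82, 89 and 92 measured at days 35, 45, 55 and 70.

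The day 21 array lay farthest from the others. Its mean distance to the other 5 was 0.455 log2 units, against 0.301 among these. Without day 21 the mean distance was 0.25 within a slide and 0.336 between slides. The remaining arrays thus grouped by slide, which is also control and day 35 against the later days, so slide and time cannot be told apart. Control and day 35 lay at 0.239, control and day 45, 55 and 70 at 0.358, 0.331 and 0.361. The SD expected from replicate spots alone was 0.083.

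**Figure D5:**
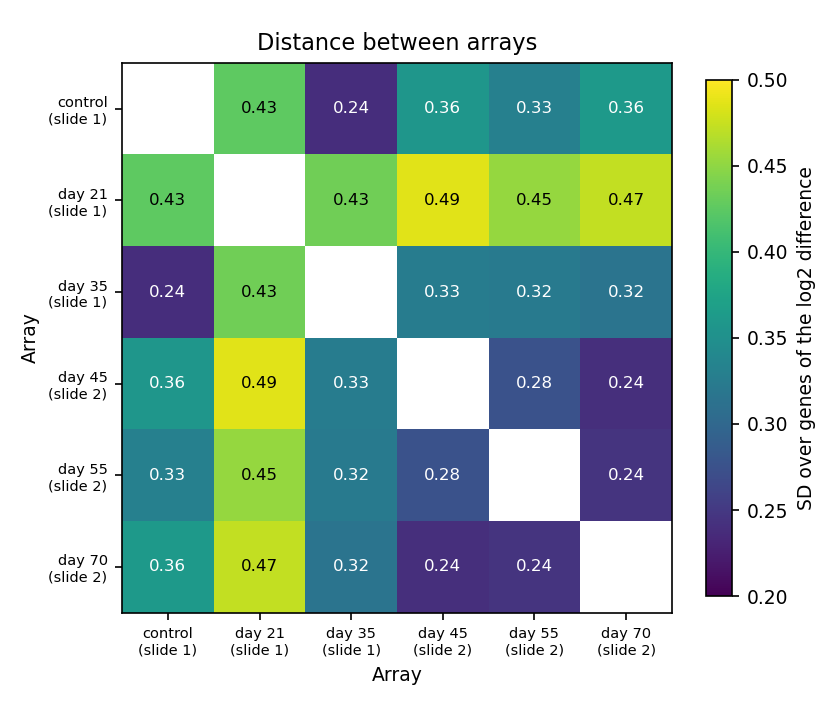
Each cell shows the SD over 12172 genes of the log2 difference between a pair of arrays, with arrays and their slide on both axes. Day 21 lay between 0.426 and 0.487 from every other array, and control and day 35, on 1 slide, were closest at 0.239.

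For 1491 pairs of probes on the same transcript at least 300 bases apart, the median difference of the upstream minus the downstream probe, against control, was -0.057, -0.022, -0.167, -0.117 and -0.106 log2 units from day 21 to day 70. Across 12172 genes, which are not independent replicates, the rank correlation of probe GC content with the difference from the control was -0.132, -0.062, -0.141, -0.328 and -0.243. The probe of Spp1 lies on rn4 chromosome 14 at 6422382 to 6422441, that of Cd68 on chromosome 10 at 56481726 to 56481785, that of Cd74 on chromosome 18 at 56765468 to 56765527, that of Ttr on chromosome 18 at 12413621 to 12413680 and that of Sostdc1 on chromosome 6 at 55070308 to 55070367.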

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

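The tests in this part were chosen only after the results were seen, except that of the sensory receptor genes, which was fixed before its result was known. A signal also appeared in data outside the comparisons, among the probes without a gene name. The probes A_64_P071088 (rn4 chromosome 18, 56764968 to 56765027), A_44_P1029805 (chromosome 7, 140175626 to 140175685) and A_64_P117363 (chromosome 5, 80980881 to 80980940) were above the control at day 21 by 2.85, 2.67 and 2.61 log2 units. The first lies beside the probe of Cd74, which starts at 56765468 on the same chromosome. Among unnamed probes well above background on both arrays, 105 were at least 2-fold higher and 128 lower at day 21, and 411, 386 and 518 were lower at days 45, 55 and 70.

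The 55 genes lower than the control at all 5 days are by definition those bright on the control array alone. On the 5 arrays without day 21, probes printed 10 times were bright on 1 array 1 time where the rate of probes printed once at the same level gives 8.8, a ratio of 0.114. That is in line with single spots that are bright by error, since averaging 10 spots removes such spots. A control pool that differs from all others was not excluded: 0 probes printed 10 times stood out on the control array, but only 2.3 were expected. No biological explanation of these 55 genes was tested.

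Many dim genes were lower at days 45, 55 and 70, and a later phase of the response to the occlusion stays open and untested. After a lowess correction of the trend with signal level, lower genes still outnumbered higher ones by 2.58 times at day 70 (462 against 179, from 922 and 92 before), which argues against that trend as the whole cause, although the correction removed many lower genes. A GC correction left 385 lower and 215 higher genes at day 70 and 295 and 189 at day 45, and upstream minus downstream probes of a transcript stood at -0.167, -0.117 and -0.106 on these arrays. Of 1335 sensory receptor genes, whose known site of expression is outside the hippocampus, 332 were compared at all 3 days. Of these 97 (29.2%) were lower at all 3, against 10.1% of other genes at their level (6.9 to 13.6 over most random draws). Weaker nonspecific signal of dim probes on these arrays would give such a share. A spot bright on the control array would too, since signal well above background there was enough to be compared. The share therefore does not decide between them. The slide cannot be told apart from the time: of the 464 genes lower at all 3 days, 199 (42.9%) were lower also against day 35, and within the second slide 99 to 127 genes were lower between 2 arrays. The rest of the 464 did not pass 2-fold against day 35 on every one of these arrays. The control array's own value, or the threshold, may have a part in those calls, which was not tested.

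Immune and glial genes were higher at day 21, and more choroid plexus in the sample is argued against by days 35 and 70, where choroid plexus genes were higher but the microglial median was at most 0.095 of theirs. A lower share of neurons would raise other cell types alike. For the microglial genes this is argued against, since their lower quartile lay 0.61 log2 units above the upper quartile of the endothelial genes. The lower quartiles of the general astrocyte (0.04) and oligodendrocyte genes (0.0) lay below that upper quartile (0.11). For these glial lists a lower share of neurons stays open. Whether it accounts for the lower synaptic genes was not tested. More meningeal tissue stays open, because meningeal genes (median 1.19, 12 of 13 measured, 1 also in the neurotrophic list) stood apart on this array and on no other. At day 45 antigen presentation and microglial genes stood apart with meningeal genes at -0.15, but at medians of 0.24 and 0.15 that turned with another baseline, too small to decide about day 21. The same holds for day 70, where antigen presentation genes stood apart at 0.09 (99.8th percentile) with meningeal genes at 0.01 (85.1st percentile). A response to the occlusion, or a lesion in some animals of the pool, may also account for the pattern and was not tested.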

How the results depend on the processing

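At day 21 the medians of synaptic vesicle, glutamate receptor, microglial, astrocyte, reactive astrocyte, oligodendrocyte, cytokine, antigen presentation, heat shock, choroid plexus and meningeal genes kept their direction and stayed outside the percentile range under all 11 alternatives. Microglial genes ranged from 1.21 to 1.58, antigen presentation genes from 1.31 to 1.73, reactive astrocyte genes from 0.92 to 1.65, cytokine genes from 0.50 to 1.20, choroid plexus genes from 0.73 to 1.60, meningeal genes from 0.90 to 1.44, synaptic vesicle genes from -0.30 to -0.26 and glutamate receptor genes from -0.30 to -0.20. Endothelium, choroid plexus and thalamus at day 35, immediate early genes and red blood cells at day 45, and choroid plexus and red blood cells at day 70 also kept their calls under all 11. The correction for level, the GC correction, the removal of genes bright on 1 array and the removal of day 21 were added after the data had been seen. No paired analysis was possible because each group had 1 array. Signal over background limits the dim genes, since only 74.5 to 80.2% of spots were well above it. Distances use genes above background on all 6 arrays, so the filters on dim probes leave them as they are, and an alternative for the channel was not run because the files hold 1 colour. A threshold or a filter changes which genes can pass, and without a filter on dim probes plain differences took the place of the bounds. The cause of the moves was not tested.

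With a 1.5-fold threshold 1066, 206, 163, 228 and 186 genes were higher at days 21, 35, 45, 55 and 70, and 734, 574, 1710, 1519 and 1830 lower. Steps gave 537 higher and 1235 lower (day 21 to 35), 231 and 1243 (35 to 45), 584 and 275 (45 to 55) and 243 and 476 (55 to 70). The counts at all 5 days were 6 higher and 165 lower, and 248 had opposite differences. With a 3-fold threshold 218, 24, 35 and 39 genes were higher at days 21 to 55, and 71, 59, 210, 196 and 274 lower at the 5 days. Steps gave 29 and 257, 44 and 127, 38 and 45, and 74 and 49. There were 0 higher and 30 lower genes at all 5 days, and 0 had opposite differences.

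Without a filter on dim probes 774, 195, 184, 340 and 236 genes were higher and 734, 507, 1934, 1373 and 1875 lower. Steps gave 440 higher (day 21 to 35), 250 higher and 1489 lower, 773 and 235, and 285 and 698. At all 5 days 4 were higher and 165 lower, and 188 had opposite differences. Limited to genes well above background on all 6 arrays, 317, 19, 18, 27 and 25 genes were higher and 111, 50, 437, 283 and 440 lower. Steps gave 62 and 377, 24 and 291, 54 and 24, and 32 and 36. Then 6 genes were lower at all 5 days, 16 had opposite differences, and 1 list stood apart above at day 55.

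Normexp correction gave 238, 12, 17, 28 and 39 higher and 27, 36, 105, 75 and 124 lower genes. Steps gave 16 and 297, 25 and 56, 31 and 25, and 43 and 34. Across all 5 days 0 were higher and 16 lower, and 2 had opposite differences. Mean distances were 0.184 within slides, 0.224 between slides, 0.347 from day 21 to the others and 0.208 among the other 5. At day 55 1 list stood apart above and 1 below.

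Quantile normalization gave 112, 200, 183 and 226 higher genes at days 35 to 70 and 297, 412 and 403 lower at days 45 to 70. Steps gave 209 higher (day 21 to 35), 196 higher and 234 lower (35 to 45), 63 higher (45 to 55) and 76 lower (55 to 70). At all 5 days 3 genes were higher, and 16 had opposite differences. The authors' deposited table gave 37 higher genes at day 35 and 112, 66, 142, 169 and 187 lower. Steps gave 67 higher and 380 lower (day 21 to 35), 115 lower (35 to 45), 46 higher (45 to 55) and 48 lower (55 to 70). Across all 5 days 0 were higher and 24 lower, 4 had opposite differences, the mean distance between slides was 0.266, and 1 list stood apart below at day 70.

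The lowess correction gave 165, 141 and 179 higher and 334, 423 and 462 lower genes at days 45, 55 and 70. The GC correction gave 99, 189, 160 and 215 higher genes at days 35 to 70 and 295, 371 and 385 lower at days 45 to 70, with 2 lists apart below at day 45. Without genes bright on 1 array 136, 36, 35, 40 and 27 genes were higher and 97 lower at day 35. At all 5 days 0 were then higher and, by the construction of the filter, 0 lower, and 11 had opposite differences. Without the day 21 array 86 genes were lower at all remaining days and 12 had opposite differences.

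With the mean of the other 5 arrays as baseline 209 genes were higher at day 35 and 12, 25, 154, 69 and 155 lower at the 5 days. Lists apart below numbered 7, 7, 6 and 8 at days 35 to 70, and 1 was apart above at day 45. Medians turned for microglia at day 45 (-0.23), antigen presentation at days 45 (-0.09) and 70 (-0.23), the glucocorticoid list at days 55 (-0.02) and 70 (-0.04) and red blood cells at day 55 (0.10). The mean of all probes of a gene left all 23 counts of genes within 1.5 times and gave 3 lists apart above at day 35, 2 above at day 45 and 4 below at day 55, and the antigen presentation median at day 70 turned to -0.02. With the mean of the list members 5 lists stood apart below at day 21, 2 above and 2 below at day 45, 1 above and 1 below at day 55, and 2 above and 1 below at day 70. It turned the hypoxia list at day 45 (-0.11), red blood cells at day 55 (0.15), the glucocorticoid list at day 70 (-0.01) and dentate gyrus genes at day 70 (-0.11). Lists without shared genes kept 141 list results and moved 2 out of the range and 2 into it.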

Other observations

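The gene lists and the test in this part were chosen after the main results were seen. Interferon response genes were higher at day 21, with a median of 1.05 log2 units (100th percentile) and 9 of 18 at least 2-fold higher. Rsad2 was higher by 2.11, Isg15 by 1.71, Ifit3 by 1.64 and Irf7, the transcription factor gene that amplifies interferon production, by 1.32. At day 35, on the same slide, the list stood below the control, with a median of -0.30 (0.0th percentile), 17 of 18 members below it and Usp18 at -0.90 and Mx1 at -0.82. Later medians were -0.02, -0.09 and -0.15 at days 45, 55 and 70, the last at the 1.1st percentile.

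Lysosomal genes had a median of 0.67 at day 21 (100th percentile), with Npc2 at 1.82, Ctsz at 1.81 and Ctsc at 1.77, and of 0.12 at day 45 (100th percentile) and 0.08 at day 70 (98.1st percentile). Cholesterol synthesis genes were below the control at day 21 in 18 of 20 members, median -0.19 (0.8th percentile), with Insig1 at -0.60. Ribosomal protein genes were above it in 19 of 20, median 0.19 (100th percentile). Markers of blood leukocytes had a median of 0.19 (94.0th percentile, 11 measured) at day 21, inside the range.

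A hypothesis was that the microglial signal of day 21 came with a change of microglial state and not of their share alone. Genes described for damage-associated microglia had a median of 0.98, with Gpnmb at 3.59 and Clec7a at a bound of 2.78. The saturated Apoe is a member of that list and counted as unchanged in its median and quartile. Genes of resting microglia had a median of 0.68, with P2ry12 at 1.17. The lower quartile of the damage-associated genes minus the upper quartile of the resting genes was -0.31, so the ranges overlapped. A larger share of microglia with no change of state could therefore not be told apart from a change of state.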
